A study of Homo sapiens with 4 samples.

How the data were processed

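RNA of 4 HCT116 lines was measured on Affymetrix arrays, 1 array per line: CST5 clones 9 and 20, untransfected cells and mock-transfected cells. Per the labels' protocols, 100 ng of total RNA per line was amplified, labelled with biotin by in vitro transcription and hybridised by the manufacturer's procedures. The array model, background correction, summarisation, normalization and annotation release are not given in the sources used here.

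The authors deposited 1 table with 24916 rows, 1 per Ensembl gene identifier, and 1 column per array, with values taken here as log2 expression. The log base is not stated. It was inferred from the range of the values, 1.03 to 12.7 over the 4 arrays, and every fold given here rests on it. Values at the same rank on different arrays differed by at most 0.222, so the arrays were on a common scale but had not been quantile-normalized at the level of these rows. How the authors grouped probes into genes sets which genes share probes with near-identical copies, and this was not checked. The table held no probe-level values, detection calls or array control probes, so background and RNA quality were not assessed, and a planned check of 3' against 5' control probes was not run. All table columns were mapped to a sample by the sample identifiers in the header. Between 207 and 265 rows had identical values on a given pair of arrays, and no pair of arrays was a duplicate.

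Gene symbols could not be assigned. The table gives identifiers alone, and of its 24916 identifiers 0 matched the reference gene table used here, whose Ensembl column was empty. The 26 gene lists fixed in advance (632 genes, such as cell cycle genes, epithelial junctions and markers of other cell types) were therefore not tested, and the CST5 transgene was not checked in each line. Genome coordinates were not used here.

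Samples were grouped by the transfection label. The control group joins mock and untransfected cells, so its spread includes any effect of mock transfection. A gene was tested if its value exceeded the array's own 40th percentile on at least 2 of the 4 arrays. This left 15131 genes and removed 9785. The comparison of 2 clones with 2 controls used limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2 residual degrees of freedom, prior degrees of freedom 3.26), with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. Genes were also counted when all 4 clone-to-control differences had 1 sign and reached 2-fold, a description without a test. The other 2 ways to split the arrays 2 against 2 were treated alike. Pairs of single arrays were described by counts and log2 differences without a test. Figures were drawn with matplotlib 3.10.9.

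The rule for named genes took, in each direction, genes past the adjusted threshold first and then those with the largest smallest clone-to-control difference, 12 each way. Because identifiers could not be named, 2 per direction are printed, and the genes that stood out between clones or between controls are not named.

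The agreement of the clones was set against 100 simulations with no shared change, in which each gene's spread came from clone 9 against clone 20 for the clones and from mock against untransfected cells for the controls. The test was tested on simulated data for the comparison of clones with controls, with 200 changed genes among 15131. It called 4.00% of 50 genes changed 1.5-fold, 54.0% of 50 changed 2-fold, 96.0% of 50 changed 4-fold and 94.0% of 50 changed 8-fold. Of 14931 unchanged genes it called 7, and 11 were 2-fold apart in all 4 differences. The simulated spreads were drawn from the fitted prior, so genes with a larger spread than that are less often called. With 200 planted genes and many calls among them, the adjustment was also less strict than in the real data, where 2 genes passed. These shares are therefore not detection rates for the real data.

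Alternatives were median centring, quantile normalization and cyclic loess of the deposited values, no filter and a filter at the 60th percentile, eBayes with a trend or robust prior, other thresholds, and leaving out each array in turn. Leaving out untransfected cells or mock equals using the other control alone. The design, the filter, the rule for named genes and these alternatives were fixed before the data were examined. The count of genes at an unadjusted p under 0.05 was followed through the alternatives only after the data were seen.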

Results

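Gene expression was measured on Affymetrix arrays in 4 lines derived from HCT116, an established human colon carcinoma cell line. Clones 9 and 20 carry a stable CST5 transgene, which encodes cystatin D, a secreted inhibitor of cysteine proteases. The other lines were untransfected and mock-transfected HCT116 cells and served as controls. Each line was represented by 1 array, so the CST5 group and the control group held 2 arrays each. The deposited table gave 24916 Ensembl gene identifiers per array, on a scale read here as log2 from its range. Array medians were 4.18 for clone 9, 4.21 for clone 20, 4.12 for untransfected cells and 4.09 for mock. Interquartile ranges were 3.53 and 3.50 in clones 9 and 20, against 3.63 in untransfected cells and 3.65 in mock. The 4 arrays limit the precision of every value, and p-values measure only the spread between these lines. No identifier could be paired with a gene symbol in the sources used here, so genes are described as groups and by identifier. For the same reason the level of CST5 itself was not analysed here, and the labels were not checked against it.

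The arrays were first compared as a whole over the 15131 genes above the filter on dim signal. The controls were the closest pair, with a Pearson correlation of 0.991 and a standard deviation of 0.218 for the log2 difference between them. Clones 9 and 20 correlated at 0.980, with a standard deviation of 0.316. Each clone correlated with each control at 0.980 or 0.981. The median absolute deviation of the log2 difference gives little weight to the most divergent genes, and was scaled to match a standard deviation for normal values. So scaled, it was 0.233 between the clones, 0.235 to 0.285 between a clone and a control and 0.169 between the controls. The first principal component held 49.0% of the variance and placed both clones on one side of both controls. The second held 34.7% and separated clone 9 from clone 20.

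The central question of the design was which genes change with CST5, and it was addressed by comparing both clones with both controls. Both CST5 lines are clones, so this comparison does not separate CST5 from the selection of clones. A set of 15 genes was at least 2-fold higher in each clone than in each control, and 8 were at least 2-fold lower in all 4 clone-to-control differences. The 15 higher genes had a median log2 difference of 1.71 (3.26-fold), with a range from 1.17 to 3.22. The 8 lower genes had a median log2 difference of -1.82 (3.54-fold), with a range from -2.68 to -1.20. In 2 of the 15 higher genes both controls lay at or below the 40th percentile of their array, and in 2 of the 8 lower genes both clones did. Background was not measured, so the folds of these 4 genes can understate the change. At 1.5-fold, 65 genes were higher and 56 lower in all 4 differences, and at 3-fold 3 genes were higher and 3 lower.

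ENSG00000081189 was higher in the clones, at 7.07 ± 0.0384 (SD, n = 2) on the log2 scale against 4.92 ± 0.0705 (SD, n = 2) in the controls. Its log2 difference was 2.15 with a standard error of 0.106, a 4.43-fold rise (limma, adjusted p = 0.0252). ENSG00000067798 was lower, at 3.45 ± 0.0499 (SD, n = 2) in the clones against 6.11 ± 0.0595 (SD, n = 2) in the controls. Its log2 difference was -2.66 with a standard error of 0.105 (limma, adjusted p = 0.0161). Its clone values, 3.41 and 3.48, lay just above the 40th percentile of their arrays, so the fall of 6.34-fold can likewise understate the change. These were the 2 genes that passed an adjusted p of 0.05 among the 15131 tested. With any 1 array left out neither passed, with limma's adjusted p from 0.110 to 0.729 for ENSG00000081189 and from 0.0842 to 0.729 for ENSG00000067798, while their log2 differences stayed between 2.10 and 2.20 and between -2.71 and -2.62.

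ENSG00000147676 had a larger mean difference, 3.22 on the log2 scale with a standard error of 0.421. Its values were 10.1 in clone 9 and 10.7 in clone 20, against 6.56 in untransfected cells and 7.77 in mock. ENSG00000163032 differed by -2.17 with a standard error of 0.234, with values of 6.11 and 5.68 in clones 9 and 20, 7.80 in untransfected cells and 8.33 in mock. Neither passed the test (limma, adjusted p = 0.255 for both). Their smallest clone-to-control differences were 2.34 and -1.69 on the log2 scale. With any 1 array left out, their log2 differences ranged from 2.62 to 3.82 and from -2.44 to -1.90.

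**Figure D1:**
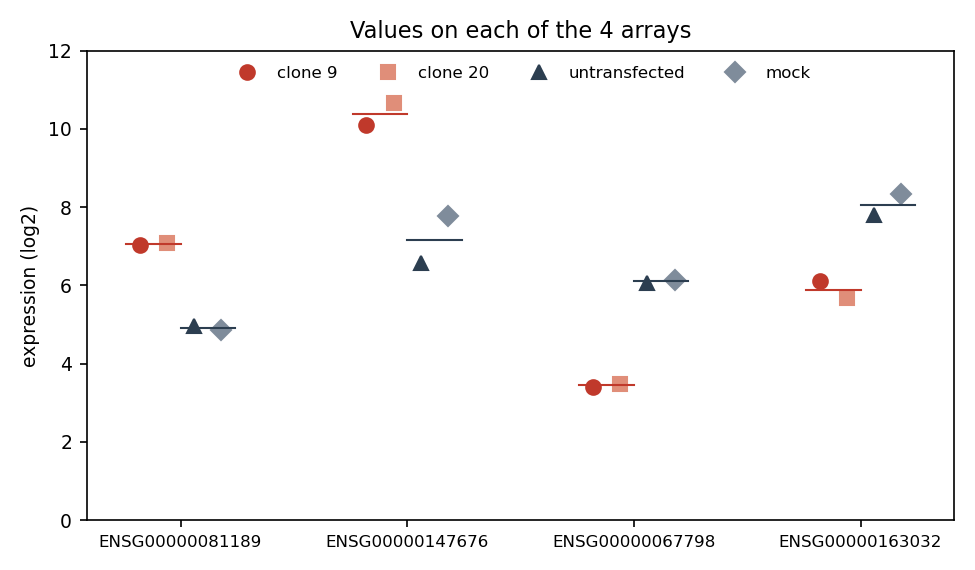
Expression on a log2 scale (vertical axis) of 4 genes, given by Ensembl identifier, on each of the 4 arrays, with 1 point per array and a short line at the mean of the CST5 clones (red) and of the controls (dark). The clones lie above both controls for the first 2 genes, by log2 means of 2.15 and 3.22, and below both for the last 2, by -2.66 and -2.17.

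A total of 2048 genes had an unadjusted p under 0.05 (limma), 1046 higher and 1002 lower in the clones, against 757 expected by chance at that threshold. This count depended on which arrays supplied the spread. With 1 array left out, it fell toward the number expected by chance without either control and rose without either clone. The total was 1726 after quantile normalization, 1756 after cyclic loess and 2494 after centring each array on its median. The split by direction depended on the scaling of the arrays: after centring each array on its median, 524 genes were higher and 1970 lower. In 48.4% of the tested genes the values of the clones did not overlap those of the controls. The share would be 33.3% if all 4 arrays varied alike with no shared change. The spread was not alike, with a standard deviation of the log2 difference of 0.316 between the clones and 0.218 between the controls. A larger spread of the clones or an array-wide trend also raises the share, so its excess alone does not show a shared change. The 4 arrays can be split 2 against 2 in 2 other ways, for which the share was 24.9% and 25.6%. Clone 9 with mock against clone 20 with untransfected cells gave 276 genes at an unadjusted p under 0.05, none past the adjusted threshold in limma, and 1 gene 2-fold apart in all 4 differences. Clone 9 with untransfected cells against clone 20 with mock gave 312 genes, none past the adjusted threshold, and 2 genes 2-fold apart. A difference shared by the clones enters the residual spread in both of these splits and lowers their counts.

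Next, each clone was set against each control, as single arrays with no replicate check. Clone 9 differed at least 2-fold from mock in 197 genes, 98 higher and 99 lower, and from untransfected cells in 198 genes, 77 higher and 121 lower. Clone 20 differed from mock in 175 genes, 84 higher and 91 lower, and from untransfected cells in 198 genes, 80 higher and 118 lower. With genes filtered at the 60th percentile, the clone 20 counts were 114 against mock and 120 against untransfected cells. Genes at least 4-fold apart numbered 14 for either clone against mock and 20 for either clone against untransfected cells. The largest of these differences was a 17.1-fold higher value in clone 20 than in untransfected cells, and the largest decrease was 16.1-fold, in clone 9 against mock.

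**Figure D2:**
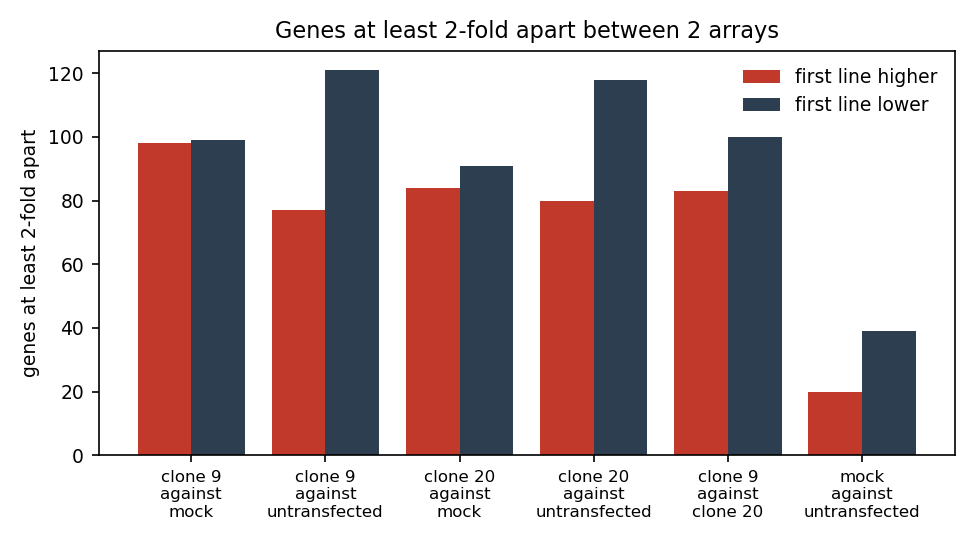
Number of genes at least 2-fold apart (vertical axis) for each pair of arrays, with 1 bar for genes higher and 1 bar for genes lower in the line named first. The 4 clone-to-control pairs and the pair of clones lie between 175 and 198 genes in total, and mock against untransfected cells at 59.

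Whether the clones shared a response was examined with comparisons that use different controls. Across genes, the log2 difference of clone 9 from mock correlated with that of clone 20 from untransfected cells at a Pearson r of 0.299 and a Spearman rho of 0.316. With the controls exchanged, r was 0.323 and rho 0.332. Simulated lines with no shared change gave 0.000510 and 0.00204 for the Pearson values, which their independent draws fix in advance. The simulation held no intensity trend or other error common to both clones, so it cannot separate such error from a shared response. After quantile normalization of the arrays r was 0.254 and 0.282. Genes are not independent replicates, so no p-value was attached. In the first pairing 18 genes were at least 2-fold higher in both clones and 12 at least 2-fold lower, against 0.518 and 0.772 expected of independent lists and 7.23 and 7.81 in the simulation, which carries the larger spread of some genes into both clones. In the same pairing 11 genes were 2-fold apart in opposite directions, and in the exchanged pairing 6 were. With mock as the control of both clones r was 0.549, and with untransfected cells it was 0.515. The simulation without a shared change gave 0.325 and 0.326 for these, from the shared array alone. The covariance above the simulated one was 0.0370 with mock shared and 0.0289 with untransfected cells shared. It was 0.0322 and 0.0340 in the pairings that shared no control. The simulated control spread came from mock against untransfected cells, so the averages of both kinds of pairing must match by construction. Their nearness is therefore no further evidence of a shared change.

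**Figure D3:**
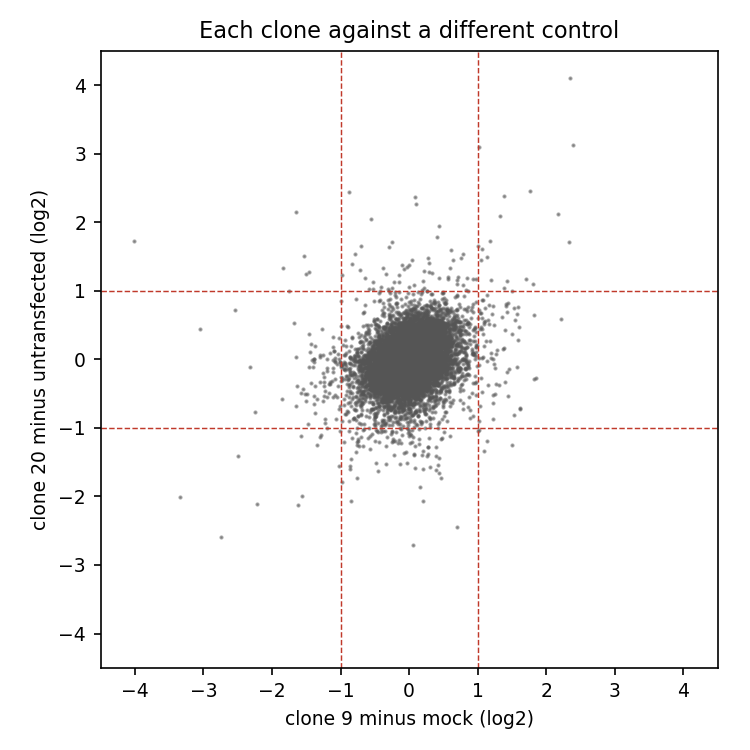
Log2 difference of clone 9 from mock (horizontal axis) and of clone 20 from untransfected cells (vertical axis), with 1 point per gene for 15131 genes and dashed lines at 2-fold. The cloud tilts upward (Pearson r of 0.299), 18 genes lie beyond both lines at the upper right and 12 at the lower left, and 11 lie in the opposite corners.

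The clones also differed from each other. Of the tested genes, 183 were at least 2-fold apart, 83 higher in clone 9 and 100 higher in clone 20, and 113 were with the filter at the 60th percentile. Of these, 19 were at least 4-fold apart, 8 higher in clone 9 and 11 higher in clone 20. The most divergent gene was 22.4-fold higher in clone 20, and the largest difference the other way was 6.53-fold. With 1 array per clone, differences between the lines and between the arrays were not separated.

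The controls gave 1 pair of lines without CST5, each measured on 1 array, and whether mock is a single clone or a pool is not given in the sources used here. Mock and untransfected cells were at least 2-fold apart in 59 genes, 20 higher and 39 lower in mock, and in 30 with the filter at the 60th percentile. Of the 39 lower genes, 4 were at least 4-fold apart. These 59 genes were 0.390% of the tested genes, against 1.16% to 1.31% for the clone-to-control pairs and 1.21% for clone 9 against clone 20. Whether mock differs from untransfected cells through transfection or through the arrays was not tested.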

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

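With 4 arrays, leaving out 1 leaves an arm with a single array, which is assumed to vary like the other group. The number of genes past limma's adjusted threshold, 2 with all arrays, was 0 without any 1 of the arrays, and the number at an unadjusted p under 0.05, which was followed only after the data were seen, ranged from 784 (without mock) to 2743 (without clone 9), with 956 without untransfected cells and 2048 with all arrays. The other alternatives, with looser adjusted p, the requirement of 2-fold, other scaling, filters or priors, kept 2 genes past the threshold. Over scaling and filter settings, genes 2-fold apart in all 4 differences numbered 11 to 15 higher and 6 to 10 lower. Of the 23 genes, 20 remained after median centring, 19 after quantile normalization, 19 after cyclic loess and 17 under the stricter filter. By construction, fewer arrays leave fewer differences to pass, and leave-one-out counts were 24 to 52 higher and 19 to 67 lower. Looser and stricter folds gave 65 and 56 genes at 1.5-fold and 3 and 3 at 3-fold, also by construction. The correlation of the clones over separate controls, 0.299 and 0.323, fell to 0.254 and 0.282 with quantile normalization, 0.262 and 0.290 with cyclic loess and 0.252 and 0.272 with no filter, and the cause was not tested. The filter at the 60th percentile, which tests fewer genes, gave 114 genes for clone 20 against mock, 120 for clone 20 against untransfected cells, 113 for clone 9 against clone 20 and 30 for mock against untransfected cells. Median centring moved the median difference of all tested genes from -0.00558 to -0.0936 and the share of higher genes at an unadjusted p under 0.05 from 51.1% to 21.0%, and quantile normalization and cyclic loess gave 51.3% and 47.3%. The planned choices between probe sets of a gene were not run, since each gene had 1 row, and the gene lists and the CST5 difference were not run for lack of gene names. No paired analysis was possible because the lines carry no shared replicate numbers. Signal over background was not known, which limits what can be said of dim genes.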

Other observations

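In this part, the tests of the intensity trend, of noise between arrays and of dim genes over all 4 arrays were chosen after the results they bear on had been seen, and those of transfection, of dim genes on any array and of clonal lines before.

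Both clones stood apart from the other lines in gene sets of their own. Clone 9 differed at least 2-fold from each of the other 3 arrays in 57 genes, 18 higher and 39 lower, and clone 20 in 41 genes, 19 higher and 22 lower. Untransfected cells stood apart in this way in 12 genes and mock in 11. The lower clone count was 3.42 times the higher control count, with an exact 95% interval of 1.76 to 7.14 that takes genes as independent. The interval does not clear the bar of 3 set for excluding noise of equal size on all arrays. Such noise would give like counts, however, and a ratio near 1 lies outside the interval. The standard deviation of the log2 difference was 0.316 between the clones and 0.218 between the controls. These values argue against noise of equal size, though not against noisier clone arrays. Noise of dim genes stays open: 98.0% of the 98 single-clone genes exceeded an array's median on at least 1 array, which the filter and the 2-fold rule largely fix. On all 4 arrays 61.2% did, against 60.9% of the 23 single-control genes. The same share over all tested genes was not computed. By mean level, a different measure, 17.7% of the tested genes lay below the median of all genes. A lasting difference between clonal lines is a candidate explanation that also stays open: with 1 array per clone, a difference between lines and a noisier RNA sample or array cannot be told apart.

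The clones read slightly higher than the controls for dim genes and slightly lower for bright ones. All 24916 genes, also those below the filter, were put in 10 equal classes by mean level. The median difference rose to 0.116 on the log2 scale in class 5 and reached -0.0860 in class 10, the brightest. Mock minus untransfected was -0.0257 and 0.0366 in the same classes. In all, 70.3% of genes in classes 3 to 6 read higher in the clones and 66.5% of those in the top 3 classes read lower. Of the genes higher at an unadjusted p under 0.05 (limma), 31.9% lay below the median level of all genes against 9.38% of the lower ones. Among all tested genes the share was 17.7%. After quantile normalization, which forces equal distributions, the shares of higher and lower genes were 17.6% and 19.5%. These values restate the pattern and do not decide its source: an array-wide intensity trend and a broad biological change in the clones cannot be told apart, because both clones lie on one side.

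The 23 genes that were 2-fold apart in all 4 differences are the set most open to follow-up once their identifiers are named. The intensity trend is argued against as their sole cause, since values at the same rank differed between arrays by at most 0.222 on the log2 scale. That is far below 2-fold. For the same reason the outcome of quantile normalization, after which 19 of the 23 still passed, was largely fixed in advance and adds little. Transfection itself was tested on the 56 genes at least 2-fold from untransfected cells in both clones, because the 23 are by selection far from mock: the mock shift was a median 0.306 of the clone shift (95% bootstrap interval over genes 0.213 to 0.367), although it was over 75% in 9 of them and the shared untransfected array raises this value. Array-to-array noise stays open as a partial cause: the other splits of the arrays gave at most 2 genes, but only 3 splits exist, and 11 unchanged genes passed in the simulated data. CST5 and the selection of clones were not separated by this design, and neither was tested.

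Genes with identifier numbers from 200000 upward made up 14.5% of the tested genes but 54.2% of the 59 genes that were 2-fold apart between mock and untransfected cells, 32 genes of which 24 were lower in mock. In the clone-to-control pairs they numbered 40 to 59, which was 20.2% to 29.9% of the genes 2-fold apart, and between the clones 44 of 183. Their share was thus highest in the control pair, but their number there, 32, was the lowest of all pairs. This cutoff was not part of the design fixed in advance. Their median absolute log2 difference between mock and untransfected cells was 0.153, against 0.110 for the other genes, and it was not computed for the other pairs.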
